A study of Mus musculus with 3 samples.

How the data were processed

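RNA of single cells was measured in 3 libraries of the mouse sinoatrial node region at E13.5, made with 10x Chromium v2 chemistry per the labels' protocols. The deposited files hold UMI counts per gene and barcode, which the authors made with Cell Ranger 3.0.1 on mm10 per the submitters' processing notes. The values were whole numbers with no normalization. The steps by which barcodes were chosen as cells are not given in the sources used here. The reference held an added GFP feature. Libraries were grouped by the genotype in the labels: Shox2Cre/+ (control), Shox2Cre/Cre (labelled Shox2-KO) and Shox2Cre/Cre with Nkx2-5F/F (labelled Double-KO), each with the R26RmTmG reporter, 1 library each. Gene positions came from GENCODE M21.

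Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs, which left 3676, 5777 and 4882 in the control and the libraries labelled Shox2-KO and Double-KO. Haemoglobin genes gave most of the UMIs in 559, 1217 and 1204 barcodes before filtering. Scrublet, run in scanpy with an expected doublet rate of 0.06, called 28, 140 and 3 barcodes, so it removed almost none from the library labelled Double-KO, and doublets were not excluded there. Kept cells had median mitochondrial shares of 2.78%, 3.53% and 2.87% and ribosomal protein shares of 27.1%, 34.1% and 31.9%. Clusters were made with Leiden at resolution 1 on 30 principal components of 2000 variable genes and 15 neighbours. Mitochondrial, ribosomal protein, haemoglobin and sex-linked genes, Shox2 and Nkx2-5 were left out of the variable genes. Each cluster was named from the marker sets of broad cell classes. The 14 sets also include pacemaker, working atrial and ventricular ones, which were used only for the subclusters of cardiomyocyte-like cells. The naming rule was adjusted after a first clustering had been seen: a marker counts when at least 25% of the cluster's cells hold it and it is at least 1.5-fold above the rest, sets are ranked by their number of such markers and then by their members among the 10 leading genes, and a cluster stays unnamed when the best set has under 3 such markers or ties in both counts, when another set has more of the leading genes, or when its depth is far below the library median and no marker is among its leading genes. Cardiomyocyte-like cells were clustered again on 1500 variable genes, also without cell cycle genes, with 20 components and resolution 0.8.

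UMIs were summed over the cells of a class in each library and divided by the class total to give CPM. Ratios between libraries carry exact binomial 95% intervals and single values exact Poisson intervals. Shares of cells carry Clopper-Pearson intervals, and a share of 0 is given with the limit that 3 counts allow. Shares of cells with a UMI were also taken after each cell with at least 3000 UMIs was thinned to that depth, which left out 156, 210 and 43 cardiomyocyte-like cells. No test across genes was run, because 1 library per genotype gives no error between libraries, and the counts of genes at least 2-fold apart in each of 5 classes describe these libraries only. The 19 gene lists, the margin of 1.5-fold, the minimum of 50 UMIs for a measured member, the filters and the named-gene rule were fixed before the data were examined. That rule takes, in each pair of libraries, the 10 genes with the largest ratio each way among genes with at least 200 UMIs in the pair and 50 CPM in a library, without genes whose level was over 5 times lower than in another class of at least 50 cells, a sign of free RNA, and without mitochondrial, ribosomal protein, haemoglobin, sex-linked and predicted genes. All measured list members may be named too. It had 2503, 2616 and 2462 genes to choose from, after 65, 71 and 78 were left out for free RNA. The ratio outside the class is printed where it was at least 1.5-fold the same way, at any level, so it can rest on levels near the floor or on free RNA. List medians were set beside those of 10000 random lists of matched abundance. Genes named for GFP-high cells, for subclusters or for identity outside these lists were chosen after their values were seen.

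GFP division, with 500 and 200 CPM as limits, was set after the distribution of GFP had been seen. After the data were seen, 12 measures of transcript GC content and length were also tried, over 8762 genes in cardiomyocyte-like, 9037 in mesenchymal, 8248 in epicardial and 7576 in endothelial cells. Adjusted values subtract a running median over 301 genes ordered by GC content, and a gene's value was set beside those of 100 genes matched in GC content and length. That subtraction also takes out the median ratio over all genes, and at the ends of the GC range the 301 genes are not centred on the gene. Cells in low-depth or doublet-like subclusters, the share of cells in subclusters dominated by 1 library, and the number of lists with a median past 1.5-fold were likewise chosen later.

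Alternatives tried were TMM factors, CPM without mitochondrial, ribosomal protein and haemoglobin genes, means over cells, stricter and no cell filters, all kept cells, thinning, other resolutions, centring each library, each library clustered on its own, other minimum UMIs, and the divisions and adjustments above. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors only. The ratios and intervals were tested on simulated data drawn by Poisson sampling from the pooled profile at each library's depth, with 200 altered genes per pair. All 4-fold changes were recovered as at least 1.5-fold, but changes of exactly 1.5-fold passed that margin in 49.2% to 55.4% of genes, 1.4% to 1.8% of unaltered genes passed that margin, and between 92.7% and 98.5% of intervals held the true ratio. Splice isoforms, allele calls and free-RNA subtraction were not analysed here.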

Results

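Single-cell transcriptomes of the mouse sinoatrial node region, taken with surrounding atrium at stage E13.5, were measured in 3 droplet libraries, 1 per genotype. The control library (titled WT) carried Cre in 1 Shox2 allele, the library labelled Shox2-KO carried Cre in both Shox2 alleles, and the library labelled Double-KO carried in addition floxed Nkx2-5 on both alleles. All 3 carried a reporter that turns on green fluorescent protein (GFP) after Cre has acted. Shox2 and Nkx2-5 encode homeodomain transcription factors, the first known for its role in the sinoatrial node and the second for its role in working myocardium. The files held 41866565 unique molecular identifiers (UMIs) in 4686 barcodes for the control, 57345300 in 8452 for the library labelled Shox2-KO and 65216648 in 6653 for the library labelled Double-KO. After filtering, 3651, 5656 and 4879 cells were kept, with median depths of 8314, 6904 and 9261 UMIs. With 1 library per genotype there was no replicate check on any difference, no test was run across genes, and a difference between genotypes is also a difference between libraries. Values are given with exact 95% intervals, Poisson for UMIs and Clopper-Pearson for shares, which cover counting error only.

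The targeted genes were read first, in cardiomyocyte-like cells, of which there were 1129 in the control, 1274 in the library labelled Shox2-KO and 721 in the library labelled Double-KO. Shox2 (ENSMUSG00000027833; mm10 chromosome 3, 66971727 to 66981771, minus strand, protein-coding) stood at 432 CPM (421 to 444) in the control, where CPM is a gene's summed UMIs scaled by the total of its class and library. It stood at 26.5 (23.6 to 29.7) in the library labelled Shox2-KO, 16.3-fold lower (14.5 to 18.4), and at 20.1 (17.3 to 23.3) in the library labelled Double-KO, 21.5-fold lower (18.5 to 25.1). Nkx2-5 (ENSMUSG00000015579; chromosome 17, 26838664 to 26845009, minus strand, protein-coding) stood at 137 (131 to 144) in the control, at 25.1 (22.3 to 28.2) in the library labelled Shox2-KO and at 168 (160 to 177) in the library labelled Double-KO. Over this class as a whole, Nkx2-5 therefore went against the Double-KO label. It was 1.23-fold higher there than in the control (1.15 to 1.32), which is under the 1.5-fold margin and did not hold with means over cells (log2 ratio -0.057, against 0.30). Over all kept cells the log2 ratio was -0.80. Those include the other classes, and cardiomyocyte-like cells made up 14.8% of them there against 30.9% in the control. Nkx2-5 was 5.46-fold lower (4.81 to 6.21; 0.157 of the control outside the class) in the library labelled Shox2-KO, in which the labels name no Nkx2-5 allele. For this reason each mutant library is called by its label throughout, and every direction below rests on those labels.

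The share of cardiomyocyte-like cells with a Shox2 UMI was 81.7% in the control, 17.0% in the library labelled Shox2-KO and 13.9% in the library labelled Double-KO, at median depths of 10404, 8655 and 12338 UMIs. For Nkx2-5 these shares were 57.8%, 16.9% and 63.1%. After each cell was thinned to 3000 UMIs the Shox2 shares were 63.2%, 7.89% and 4.13%, and the Nkx2-5 shares 32.5%, 5.92% and 35.8%. Endothelial or endocardial cells, which should lack both genes and had median depths of 7678, 6955 and 11146 UMIs, gave thinned Shox2 shares of 1.41% in the control, 0.0903% in the library labelled Shox2-KO, and 0 of 403 in the library labelled Double-KO, which allows up to 0.744%. Their thinned Nkx2-5 shares were 0 of 426 in the control, which allows up to 0.704%, then 0.0903% and 0.744%. Among thinned control cardiomyocyte-like cells, 21.1% (18.5 to 23.8) held UMIs of Shox2 and Nkx2-5 together, against 20.5% for the product of the separate shares. The joint share was 0.188% in the library labelled Shox2-KO and 0.147% in the library labelled Double-KO, each below the product of the separate shares there.

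Because Nkx2-5 was to be removed only where Shox2-Cre had acted, cardiomyocyte-like cells with at least 3000 UMIs were also divided by GFP, a division added after the data were seen. Cells with at least 500 GFP CPM are called GFP-high (423 in the control, 599 in the library labelled Shox2-KO, 183 in the library labelled Double-KO) and cells under 200 GFP-low (456, 437 and 469), with 94, 28 and 26 cells between. In GFP-high cells Nkx2-5 stood at 121 CPM in the control, 18.2 in the library labelled Shox2-KO and 11.4 in the library labelled Double-KO, which was 6.65-fold (5.42 to 8.23) and 10.6-fold (7.32 to 16.0) below the control. In GFP-low cells it stood at 144, 31.5 and 232. Within the library labelled Double-KO, Nkx2-5 was 20.3-fold lower (14.1 to 30.4) in GFP-high than in GFP-low cells. The same ratio of GFP-high to GFP-low cells was 0.845 (0.761 to 0.937) in the control and 0.579 (0.448 to 0.746) in the library labelled Shox2-KO. The GFP-low cells of the control still held 286 Shox2 CPM, against 575 in its GFP-high cells, so GFP did not mark every cell with Shox2. GFP-low cells of the libraries labelled Shox2-KO and Double-KO held 6.33 and 2.98. The control was heterozygous for Shox2-Cre and the mutant libraries homozygous. The GFP division may therefore not give like sets of cells in control and mutant libraries, which was not tested.

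**Figure D1:**
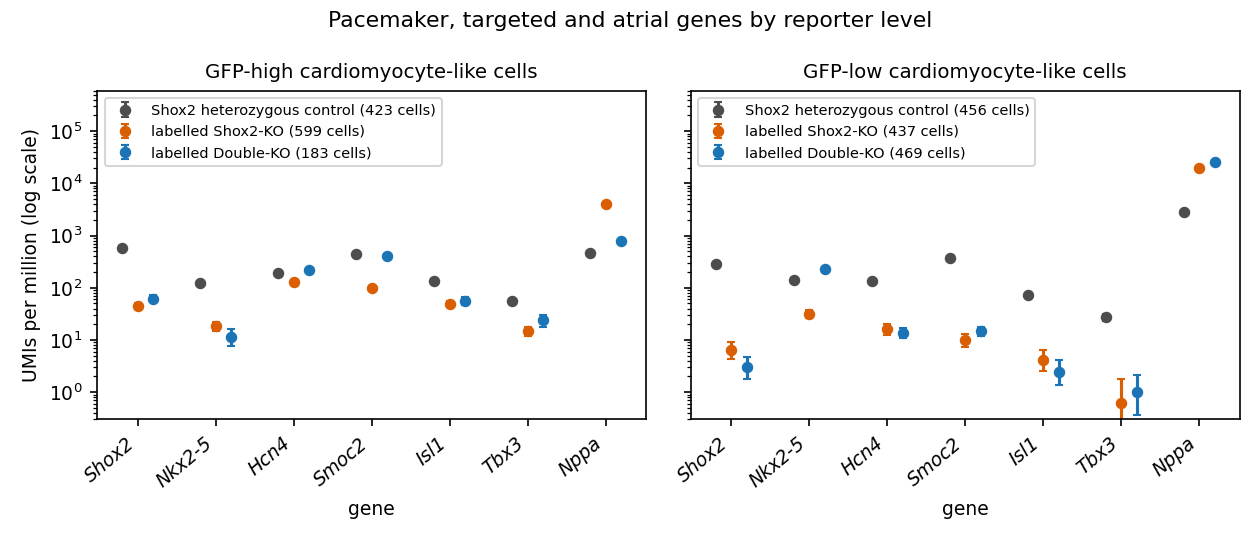
CPM (log scale) of Shox2, Nkx2-5, Hcn4, Smoc2, Isl1, Tbx3 and Nppa in GFP-high and GFP-low cardiomyocyte-like cells, 1 point per library, with exact 95% Poisson intervals as bars. In GFP-high cells Nkx2-5 lies at 121, 18.2 and 11.4 CPM in the control and the libraries labelled Shox2-KO and Double-KO, and in GFP-low cells at 144, 31.5 and 232.

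The library labelled Shox2-KO was compared with the control to ask which cardiomyocyte genes differ when Shox2 is lost. Transcription factors of the node were lower with Shox2. Isl1, which marks pacemaker precursors, stood at 28.1 against 102 CPM (3.64-fold lower, 3.22 to 4.13), Tbx3, a repressor of working myocardial genes, at 8.13 against 42.1 (5.17-fold lower, 4.14 to 6.52; 0.315 of the control in cells outside the class), and Tbx18 at 42.6 against 65.5. All 4 members of this list, of which Shox2, the deleted gene, is 1, were at least 1.5-fold lower, with a median log2 ratio of -2.12 (percentile 0.02 among 10000 random lists of matched abundance, a description of these libraries and not a test). Of 8 measured channel and coupling genes, 6 were lower and 0 higher by that margin (median -0.87, percentile 0.42). Hcn4, the main pacemaker channel, was 2.18-fold lower (2.01 to 2.36) and the calcium channel subunit Cacna2d2 3.27-fold, and outside the class their ratios were 0.443 and 0.342. Of 10 other node-enriched genes 7 were lower (median -1.36, percentile 0.00), led by Smoc2, which encodes a matricellular protein, at 57.6 against 395 (6.86-fold lower, 6.32 to 7.45; 0.445 outside the class). Igfbp5 was 2.99-fold lower (0.595 outside the class) and Cpne5 3.29-fold (0.252).

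Working atrial genes divided in that comparison. Nppa, the gene for atrial natriuretic peptide, stood at 11490 against 1617 CPM, 7.11-fold higher (7.002 to 7.213), and was 6.54-fold higher outside the class. Bmp10, an atrial ligand of the bone morphogenetic protein (BMP) family, stood at 65.0 against 1.84, 35.4-fold higher (23.4 to 56.2; 1.62-fold outside), and the gap junction genes Gja1 and Gja5 were 3.06-fold and 1.71-fold higher. Nppb (1.91-fold), Stard10 (2.33-fold; 0.275 outside the class) and Kcnk3 (1.58-fold; 0.513) were lower, so that 5 of 12 members were higher and 3 lower (median 0.29, percentile 99.95). That median was -0.001 under the stricter cell filter, where the median over all genes was -0.508, against -0.265 in the reported setting. Over all kept cells, which include the other classes, the working atrial median was -0.13. Of 5 left-right identity genes 3 were higher, among them Nppa and Bmp10, and 2 lower, among them Adm at 18.9 against 52.99 (median 0.89, percentile 100). The core cardiac transcription factors held 5 lower and 2 higher of 12 (median -0.52, percentile 2.75), with Tbx20 2.65-fold higher (1.94-fold outside the class) and Tbx5, an upstream regulator of Nppa, 1.92-fold lower (0.416 outside). The ventricular light chain gene Myl2 was 32.2-fold lower (24.7 to 42.8; 7.08-fold outside the class) and Myl3 1.60-fold higher, in a list of 3 with 2 lower (median -2.27, percentile 0.17).

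Further lists described signalling, metabolism and cell state in the same comparison. Of 9 genes of BMP signalling and response 5 were lower and 0 higher (median -0.98, percentile 0.04), with Bmp4 at 16.6 against 67.4 CPM, Bmp2 4.94-fold lower (0.604 outside the class) and Id2, a target of the pathway, at 122 against 336. Glycolysis and hypoxia genes had 3 of 14 higher and 1 lower (median 0.52, percentile 100), with Eno1 1.87-fold and the hypoxia-induced Bnip3 1.63-fold higher, and 2.15-fold and 2.55-fold higher outside the class. Of 13 dissociation stress genes 7 were lower and 1 higher (median -0.92, percentile 0.01), with Ier2 4.98-fold and Junb 3.27-fold lower (0.271 and 0.390 outside the class). Of 9 p53 and apoptosis genes 5 were lower (median -0.59, percentile 5.11), and of 4 Notch genes 2 were lower (median -0.45, percentile 24.6). Sarcomere genes were close to level, with 2 of 16 higher and 0 lower (median -0.03, percentile 8.47), of which the skeletal actin gene Acta1 was 5.94-fold higher (1.83-fold outside). Calcium handling had 1 higher and 1 lower of 12 (median -0.10, percentile 41.7), and cell cycle genes 1 higher and 1 lower of 18 (median 0.04, percentile 98.6). Fatty acid oxidation had 1 of 10 lower (median -0.27, percentile 16.3), and oxidative phosphorylation 2 of 15 lower (median -0.09, percentile 4.29), with Uqcrfs1 4.91-fold lower (0.120 outside the class). Extracellular matrix genes had 1 higher and 2 lower of 13 (median -0.32, percentile 27.8), and the 5 sex-linked genes had 0 past the margin either way (median 0.10, percentile 89.4).

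By the rule fixed before the data were examined, the 10 genes with the largest ratio each way were named. The higher ones were Uts2b, a urotensin peptide gene (44.6-fold, 32.9 to 62.1), Bmp10, the fast skeletal troponin genes Tnnt3 (13.1-fold; 1.51-fold outside the class) and Tnni2 (6.78-fold), Nmrk2 (10.1-fold; 1.87-fold outside), Nppa, Acta1, the angiopoietin gene Angpt1 (3.92-fold), the potassium channel subunit Kcne1 (3.55-fold) and Frmd5 (3.29-fold). No ratio outside the class could be formed for Uts2b, which had no UMI there in the control. The lower ones were Scand1 (108-fold), Dapk3 (46.5-fold), Nrtn (42.7-fold), Myl2, Eef1a2 (30.8-fold), Fbxl22 (22.1-fold), the BMP and activin antagonist Fst (21.9-fold), Pcbd2 (16.4-fold), Shox2 and Chchd10 (16.3-fold). All 10 were also lower outside the class, by 192-fold for Scand1, 45.7-fold for Dapk3, 33.4-fold for Chchd10, 23.0-fold for Eef1a2, 21.5-fold for Pcbd2, 21.2-fold for Nrtn, 10.3-fold for Fbxl22, 9.02-fold for Shox2, 7.30-fold for Fst and 7.08-fold for Myl2. Control levels there were 203 CPM for Scand1, 62.1 for Pcbd2, 51.0 for Dapk3 and 43.5 for Chchd10. For the other genes they were 17.9 or less, down to 1.43 for Eef1a2, where free RNA was not excluded. Myl2, Fst, Shox2 and Eef1a2, with Nkx2-5 and Cpne5, were among the leading genes of cardiomyocyte-like cluster 10. It held 463 cells of the control, 4 of the library labelled Shox2-KO and 58 of that labelled Double-KO. For these genes, a different make-up of the class and a different level within like cells were not told apart. In each of 5 cell classes separately, 185 of 3064 genes were at least 2-fold lower in the library labelled Shox2-KO and 3 were 2-fold or more higher. Across genes, which are not independent replicates, the ratio was lower with higher GC content of the richest stretch of 100 nt in the transcript (Spearman's rho -0.335 in cardiomyocyte-like cells, -0.496 in mesenchymal and -0.45 in endothelial cells). This was the strongest of the 12 measures tried, and for the GC content of the whole transcript rho was -0.219, -0.114 and -0.096. The median over all measured genes was -0.27. With TMM factors it was 0.02, and the medians of sarcomere, calcium handling, fatty acid oxidation and oxidative phosphorylation genes were above 0. After adjustment for transcript GC content the channel median was -0.57, the working atrial median 0.53, Nkx2-5 -1.53 and Shox2 -3.80 on the log2 scale. The same adjustment gave medians of -0.34 for BMP, -0.57 for stress, -0.23 for p53 and -0.28 for core cardiac transcription factor genes and a ratio of -0.40 for Tbx18. The channel, BMP, stress and p53 medians and Tbx18 thereby came inside the 1.5-fold margin, where the core factors already lay. The glycolysis and hypoxia median moved past that margin, from 0.52 to 0.80. Hcn4 stood at -0.70 after this adjustment and at -0.58 with the trend in the richest 100 nt subtracted. Among 100 genes matched to Hcn4 in GC content and length, 7% were at or below its ratio, against 2% for Tbx3 and 1% for Isl1. The adjustment also takes out the median over all measured genes, so these moves do not separate a GC trend from that shift. Over all kept cells the left-right median was -0.011.

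**Figure D2:**
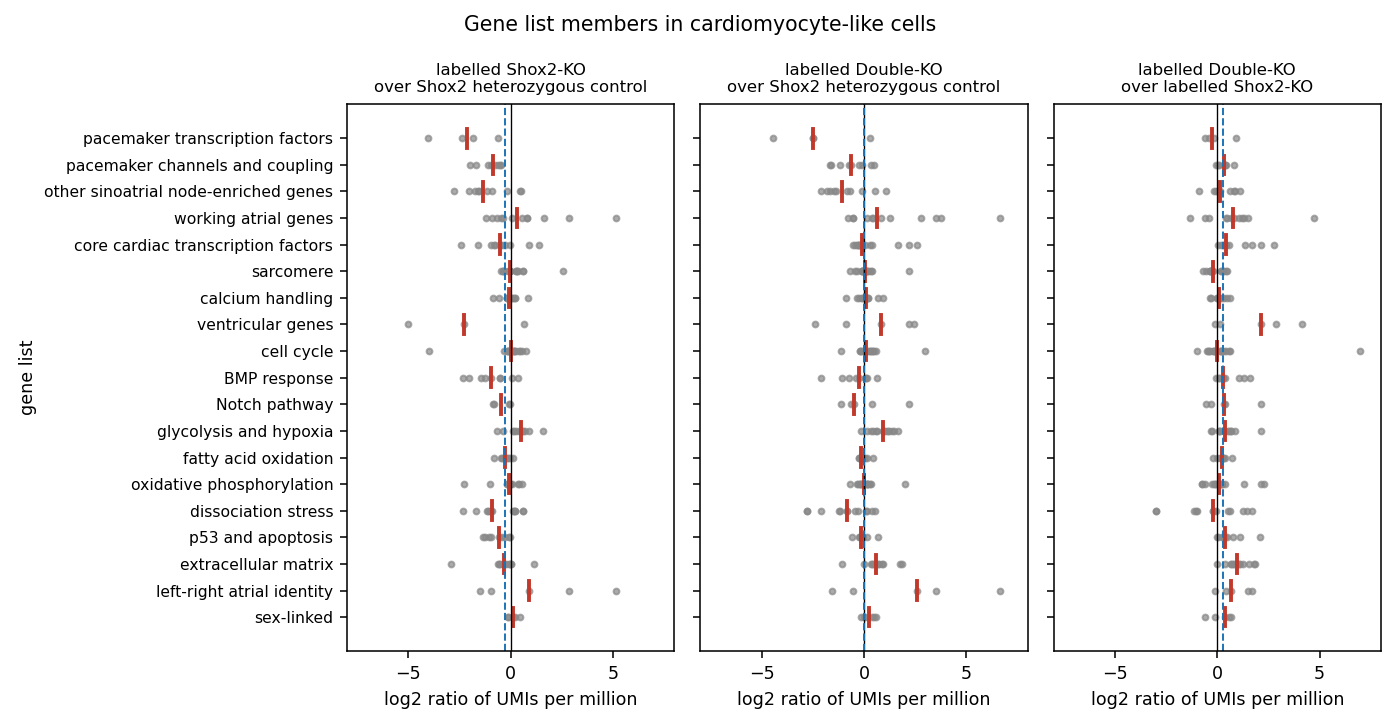
Log2 ratios of CPM in cardiomyocyte-like cells for the members of 19 gene lists, in 1 panel per pair of libraries. Grey dots are genes, red bars list medians and dashed blue lines the median over all measured genes; the pacemaker transcription factor median lies at -2.12 and -2.50 against the control and the working atrial median at 0.29 and 0.64.

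The library labelled Double-KO was compared with the control to ask how cardiomyocyte genes differ with the loss of both factors; since Nkx2-5 was low only in GFP-high cells, the whole class mixes cells with and without it. Nppa stood at 18420 CPM (11.4-fold higher, 11.2 to 11.6; 10.6-fold outside the class), Nppb, the gene for B-type natriuretic peptide, at 1185 against 86.4 (13.7-fold, 12.9 to 14.6; 21.04-fold outside), Bmp10 at 182 against 1.84 (99.02-fold, 65.8 to 157; 3.95-fold outside) and Gja1 at 224 against 32.1 (6.98-fold, 6.27 to 7.79). Of 12 working atrial genes 6 were higher and 1 lower (median 0.64, percentile 100), and over all kept cells, which include the other classes, the median was -0.28. Pacemaker transcription factors had 3 of 4 lower, Shox2 included (median -2.50, percentile 0.00), with Isl1 5.61-fold (4.76 to 6.65) and Tbx3 5.70-fold lower (4.41 to 7.48), while Tbx18 stood at 80.7 against 65.5. Of 9 channel and coupling genes 5 were lower (median -0.63, percentile 0.10), among them Hcn4 (2.27-fold, 2.08 to 2.48) and Cacna2d2 (3.11-fold; 0.488 outside the class). Of 10 other node-enriched genes 7 were lower and 1 higher (median -1.10, percentile 0.00), with the calcium sensor gene Vsnl1 3.51-fold (0.329 outside the class) and Smoc2 3.16-fold lower.

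Restricted to GFP-high cells, the same comparison gave smaller differences in several of these genes. There Hcn4 stood at 222 CPM against 193, Smoc2 at 398 against 440, Nppb at 37.8 against 40.8 and Nppa at 771 against 457. The channel median was 0.046 (-0.052 after GC content adjustment) and the working atrial median -0.10, beside 0.101 over all genes measured in these cells. Past the 1.5-fold margin, 2 of 8 channel genes were higher and 2 lower, and 3 of 12 working atrial genes were higher and 3 lower. Isl1 at 56.0 against 136 and Tbx3 at 23.6 against 55.0 stayed lower. Cacna2d2 at 261 against 446 and Vsnl1 at 344 against 587 also stayed lower, past that margin. Bmp10 at 31.9 against 0.706 and Gja1 at 102 against 11.3 stayed higher. Gja5 was lower, at 12.6 against 33.2, and Tbx18 stood at 201 against 54.0. In GFP-low cells Hcn4 stood at 13.6 against 134, Nppa at 25780 against 2813 and Nppb at 1669 against 120.

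Other lists differed as follows in the whole class of the library labelled Double-KO against the control. Glycolysis and hypoxia genes were higher in 10 of 14 and lower in 0 (median 0.94, percentile 100), led by Vegfa, an angiogenic factor (2.79-fold), Hk2, a hexokinase (2.59-fold), and the glucose transporter gene Slc2a1 (2.37-fold; 2.78-fold outside the class). In GFP-high cells their median was 0.156, inside the 1.5-fold margin, with 4 of 13 higher and 1 lower, and in GFP-low cells 1.156. Left-right identity genes were higher in 3 of 5 and lower in 1 (median 2.59, percentile 100), with Nppa and Bmp10 among the higher ones. Extracellular matrix genes were higher in 6 of 13 and lower in 1 (median 0.58, percentile 100), with Fn1, the fibronectin gene, at 103 against 29.0, but Fn1 stood at 467 outside the class, and the collagen gene Col1a1 at 1136 against 102 in it. A subcluster led by Eln, Dcn and Col1a2 held 34 cells of that library and 5 of the control, and without it and the other low-depth and doublet-like subclusters the matrix median was 0.186. In GFP-high cells it was 1.12 (0.993 after GC content adjustment), with 9 of 12 members higher and 0 lower. Dissociation stress genes were lower in 7 of 13 (median -0.81, percentile 0.00), with the heat shock genes Hspa1a 6.85-fold (5.33 to 8.92) and Dnajb1 4.29-fold lower. Core cardiac transcription factors were higher in 3 of 13 (median -0.10, percentile 26.1), with Tbx20 at 342 against 108, and ventricular genes higher in 3 and lower in 2 of 5 (median 0.81, percentile 99.9), with Myl3 1.75-fold higher and Myl2 1.86-fold lower. That ventricular median turned to -1.225 with cells thinned to 3000 UMIs, -0.895 with at least 200 UMIs per member, -0.02 without low-depth and doublet-like subclusters and -1.99 in GFP-high cells, and the stress median to 0.068 over all kept cells. BMP genes were lower in 3 of 9 and higher in 1 (median -0.25, percentile 6.49), with Bmp4 4.28-fold lower (3.58 to 5.15), and Notch genes lower in 2 of 5 and higher in 1 (median -0.48, percentile 1.36). In GFP-high cells the BMP median was 0.267, with 3 of 9 higher and 2 lower. Sarcomere genes had 1 higher and 1 lower of 16 (median 0.03, percentile 63.7), calcium handling 2 higher and 1 lower of 12 (median 0.08, percentile 91.5), and cell cycle 1 and 1 of 18 (median 0.10, percentile 92.3). Fatty acid oxidation had 0 past the margin of 10 (median -0.12, percentile 26), oxidative phosphorylation 1 and 1 of 16 (median -0.001, percentile 61.9), p53 and apoptosis 1 higher of 9 (median -0.14, percentile 21.1) and sex-linked genes 0 of 6 (median 0.24, percentile 90.9). The median over all measured genes was -0.02, and with TMM factors that of oxidative phosphorylation was 0.009.

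The named genes of this comparison began with Bmp10, Uts2b (34.2-fold), Nppb, Nppa, the epithelial keratin gene Krt19 (8.10-fold; 1.56-fold outside the class), Gja1, the potassium channel gene Kcnh7 (5.69-fold; 1.78-fold outside), Acta1 (4.65-fold; 3.78-fold outside), the potassium channel regulator Abcc9 (4.47-fold) and the integrin gene Itga1 (4.06-fold). The lower ones were Shox2 (4.72-fold lower outside the class), Rgs4, a regulator of G protein signalling (9.57-fold, 8.0 to 11.6), Hspa1a, the DNA repair gene Mgmt (5.96-fold), Isl1, the thrombomodulin gene Thbd (5.34-fold), Lxn (4.95-fold), Tenm4 (4.78-fold), Dnajb1 (1.57-fold outside) and Bmp4. Fewer genes differed in every class here than in the other pairs of libraries, with 8 of 4290 at least 2-fold lower and 4 higher.

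The libraries labelled Double-KO and Shox2-KO were compared to ask what differs when Nkx2-5 is lost in addition to Shox2. In GFP-high cells, where Nkx2-5 was 1.59-fold lower (1.05 to 2.49) in the library labelled Double-KO, several node genes were higher there. Smoc2 stood at 398 against 97.9 CPM (4.07-fold higher, 3.67 to 4.52), Tbx18 at 201 against 55.5 (3.63-fold, 3.15 to 4.18), Hcn4 at 222 against 131 (1.69-fold, 1.52 to 1.89), Cacna2d2 at 261 against 160 (1.63-fold, 1.47 to 1.80) and Tbx3 at 23.6 against 14.6 (1.62-fold, 1.14 to 2.27). Isl1 at 56.0 against 49.2 differed by less than its counting error (1.14-fold, 0.924 to 1.40). Subclusters named pacemaker-like held 41.5% of GFP-high cells of the library labelled Double-KO and 23.5% of those of the library labelled Shox2-KO. That name carries a limit in the latter library, given below. With that limit, Tbx18 in GFP-high cells stood at 172 against 122 CPM inside those subclusters and at 221.5 against 39.8 outside them. Tbx3 stood at 49.8 against 17.8 inside and, the other way, at 5.35 against 13.9 outside. Hcn4 and Smoc2 were higher in the library labelled Double-KO in both parts. Over all GFP-high cells the channel median was 0.73 and that of other node-enriched genes 0.82, while Nppa was 5.18-fold lower (4.94 to 5.42) and Gja5, an atrial gap junction gene, 2.96-fold lower. The working atrial median was -0.09, with 3 of 12 higher and 4 lower. Higher medians were not limited to node genes, with 0.813 for BMP genes (7 of 9 higher), 0.77 for p53 and apoptosis (5 of 9) and 1.168 for sex-linked genes (3 of 4 higher, 1 lower), or 0.444, 0.021 and 1.113 after GC content adjustment. The median over all genes measured in these cells was 0.328, and GC content adjustment gave 0.41 for channels and 0.484 for other node-enriched genes, both inside the 1.5-fold margin, while with the trend in the richest 100 nt subtracted these were 0.354, inside it, and 0.609, past it. With the GC content trend subtracted, the log2 ratios were 0.28 for Hcn4, 0.34 for Cacna2d2 and 0.33 for Tbx3, each under the 1.5-fold margin, 1.65 for Smoc2, 1.58 for Tbx18 and -1.60 for Nkx2-5. With the trend in the richest 100 nt subtracted, Hcn4 stood at 0.12, Cacna2d2 at 0.045 and Nkx2-5 at -1.37.

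Over the whole class Nkx2-5 was 6.70-fold higher (5.91 to 7.63) in the library labelled Double-KO, against that label. Working atrial genes were higher in 7 of 12 and lower in 2 (median 0.74, percentile 100, against -0.09 in GFP-high cells), with Nppb 26.2-fold higher (24.0 to 28.6; 26.4-fold outside the class), Bmp10 2.80-fold and Gja1 2.28-fold higher (2.44-fold and 1.63-fold outside), and Kcna5 2.504-fold lower. Pacemaker transcription factors had 1 higher and 1 lower of 4 (median -0.27, percentile 0.86), with Tbx18 1.90-fold higher and Isl1 1.54-fold lower. Channels had 1 of 8 higher (median 0.35, percentile 79.4), which was Gjc1, a gap junction gene (1.77-fold; 3.02-fold outside the class). Other node-enriched genes had 4 of 10 higher and 1 lower (median 0.11, percentile 33), with Smoc2 2.17-fold higher (3.88-fold outside) and Vsnl1 1.84-fold lower. Core cardiac transcription factors had 4 of 13 higher (median 0.41, percentile 90.7), including Nkx2-5 (6.77-fold higher outside the class). Extracellular matrix genes were higher in 11 of 13 (median 0.98, percentile 99.98), with Vcan, the versican gene, 3.58-fold (1.73-fold outside) and Col4a1 2.39-fold higher, the latter at 66.7 in the class against 107 outside it. Without low-depth and doublet-like subclusters that median was 0.543, and in GFP-high cells 1.42 (0.979 after GC content adjustment), with 11 of 12 higher. Left-right genes were higher in 3 of 5 (median 0.68, percentile 98.3), and ventricular genes in 3 of 5 (median 2.13, percentile 99.98), with Myl2 17.3-fold higher (13.2 to 23.2; 5.44-fold outside). Myl2 was 15.3-fold higher in GFP-low cells, but in GFP-high cells its log2 ratio was -2.11, on 1 UMI against 10. The ventricular median was -0.035 over all kept cells and -0.076 in GFP-low cells. With the GC content trend subtracted the working atrial median was 0.38, the channel median 0.079 and that of other node-enriched genes -0.15.

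Glycolysis and hypoxia genes were higher in 4 of 14 between these libraries (median 0.36, percentile 98.9), with Vegfa 4.46-fold higher (2.09-fold outside the class), and BMP genes in 3 of 9 (median 0.28, percentile 66.4), with Bmp2 3.01-fold higher. The glycolysis and hypoxia median was -0.157 in GFP-high cells, 0.691 in GFP-low cells and 0.095 over the class after GC content adjustment. Dissociation stress genes divided, with 4 higher and 5 lower of 13 (median -0.21, percentile 0.25), as Dusp1 was 3.26-fold higher (3.99-fold outside) and Hspa1a 8.05-fold lower (6.271 to 10.49; 1.69-fold lower outside). Their median had the other sign in GFP-high cells (0.365, 5 higher and 5 lower of 13) and in GFP-low cells (0.342, 5 higher and 1 lower of 12). Oxidative phosphorylation had 3 higher and 3 lower of 16 (median 0.09, percentile 89.4), with Uqcrfs1 4.88-fold higher (7.92-fold outside) and Cycs, the cytochrome c gene, 1.67-fold lower. Sarcomere genes had 1 of 16 lower (median -0.23, percentile 6.56), which was Myl7, the atrial light chain gene (1.61-fold), and calcium handling 1 of 12 higher (median 0.09, percentile 70.1). Cell cycle genes had 2 higher and 1 lower of 18 (median 0.00, percentile 6.16), fatty acid oxidation 1 higher of 10 (median 0.25, percentile 77.8), p53 and apoptosis 3 higher of 9 (median 0.37, percentile 72.8), Notch 1 higher of 5 (median 0.32, percentile 52.6) and sex-linked genes 1 each way of 5 (median 0.39, percentile 78.7). The median over all measured genes was 0.25. With TMM factors it was -0.02, and the medians of other node-enriched, calcium handling, cell cycle, fatty acid oxidation and oxidative phosphorylation genes were below 0.

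The named genes higher in the library labelled Double-KO than in that labelled Shox2-KO were Scand1 (83.3-fold), Nrtn (43.9-fold), Fbxl22 (26.4-fold), Nppb, Myl2, Pgp (15.2-fold), Chchd10 (14.4-fold), Pcbd2 (14.0-fold), Mrps24 (12.1-fold) and Pgls (11.1-fold). All 10 were higher outside the class too, by 169-fold for Scand1, 33.4-fold for Nrtn, 32.0-fold for Chchd10, 26.4-fold for Nppb, 22.0-fold for Pgp, 17.8-fold for Pcbd2, 16.1-fold for Pgls, 15.4-fold for Mrps24, 14.4-fold for Fbxl22 and 5.44-fold for Myl2. Levels there in the library labelled Double-KO were 10.7 CPM or less for Fbxl22, Nrtn, Nppb and Myl2, where free RNA was not excluded. They were 41.7 or more for the others. The lower ones were Hspa1a, Uqcrb (2.93-fold; 3.52-fold outside the class), Lockd (2.51-fold), Glo1 (2.28-fold; 2.35-fold), Itgb3bp (2.27-fold; 2.11-fold), the stress-responsive Ankrd1 (2.24-fold; 4.73-fold), Dnajb1 (2.22-fold), Calca (2.21-fold), Dctn6 (2.17-fold; 2.08-fold) and Tnfrsf12a (2.14-fold; 1.80-fold). In each of the 5 classes 249 of 4324 genes were at least 2-fold higher and 5 lower. In the 31 genes with transcript GC content between 65% and 70% the median log2 ratio was 1.99, against -1.82 for the library labelled Shox2-KO over the control and -0.11 for the library labelled Double-KO over the control.

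**Figure D3:**
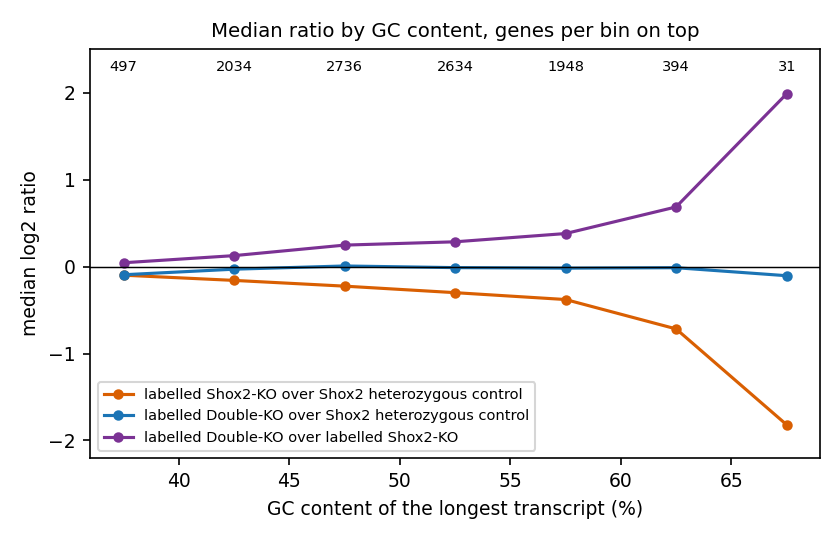
Median log2 ratio of CPM in cardiomyocyte-like cells against the GC content of the longest transcript (percent, in bins of 5), 1 line per pair of libraries, with the number of genes per bin at the top. In the bin from 65% to 70% the medians lie at -1.82, -0.11 and 1.99.

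Cell types were counted to describe what each dissected region held. Cardiomyocyte-like cells made up 30.9% of cells in the control (29.4 to 32.5), 22.5% in the library labelled Shox2-KO (21.4 to 23.6) and 14.8% in the library labelled Double-KO (13.8 to 15.8). They came mostly from clusters 10 and 14 in the control, 4 and 12 in the library labelled Shox2-KO, and from several clusters in the library labelled Double-KO, of which cluster 21 held the most with 310 cells. Mesenchymal cells made up 23.6%, 28.7% and 31.1%, epicardial cells 13.3%, 17.1% and 14.6%, and endothelial or endocardial cells 13.3%, 22.1% and 8.73%. Smooth muscle cells made up 4.16%, 4.19% and 7.56%, macrophages or other immune cells 3.31%, 2.92% and 3.81%, erythroid cells 1.86%, 0.831% and 1.93%, neuronal cells 0.52%, 0.583% and 1.52%, and Schwann cells 0.712%, 0.69% and 1.13%. Lung or foregut epithelial cells, which lie outside the heart, made up, by cluster, 1.64% in the control, 1.48% in the library labelled Double-KO and 0 of 5656 cells in the library labelled Shox2-KO, which allows up to 0.053%. Unnamed clusters held 6.68%, 0.371% and 13.4%. Dissection, tissue loss and capture enter these shares, so they do not count cells in the heart.

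Within cardiomyocyte-like cells, subclusters 4, 6, 7 and 8 met the naming rule for pacemaker-like cells. Subcluster 8, with 159 cells, all of the library labelled Shox2-KO, had no node marker among its 10 leading genes, which included the matrix genes Col3a1, Cthrc1 and Mfap2. Shares under that name in that library carry this limit wherever they stand beside those of another library, and they do not measure a difference in make-up. The 165 cells of that library under the name still held Hcn4 at 194 CPM, Smoc2 at 202 and Isl1 at 104. Control cells of that name held 255, 695 and 169. Nppa stood at 129 in those 165 cells, against 11490 in the whole class of that library. Of all 3124 cells, 1868 (59.8%, 58.1 to 61.5) lay in subclusters with at least 80% of their cells from 1 library. In thinned cells Hcn4 and Nppa were found together in 2.78% of the control, 3.95% of the library labelled Shox2-KO and 5.61% of the library labelled Double-KO, below the products of their shares of 7.88%, 10.8% and 10.8%. Nkx2-5 and Nppa were found together in 12.6%, 4.70% and 33.8%, above the products of their shares in each library. Of endothelial cells, which should lack Nppa, 3.29%, 17.5% and 28.5% held an Nppa UMI at the same thinned depth, against 24.3%, 58.5% and 77.3% of cardiomyocyte-like cells.

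The remaining genes read beside the targets were Hcn4 (ENSMUSG00000032338; chromosome 9, 58823412 to 58863175), Nppa (ENSMUSG00000041616; chromosome 4, 148000722 to 148002079), Isl1 (ENSMUSG00000042258; chromosome 13, 116298281 to 116309689), Tbx3 (ENSMUSG00000018604; chromosome 5, 119670669 to 119684724), Tbx18 (ENSMUSG00000032419; chromosome 9, 87702800 to 87731260) and Bmp10 (ENSMUSG00000030046; chromosome 6, 87428994 to 87437677), all protein-coding in mm10 with identifiers from the files and positions from GENCODE M21.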

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

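All tests of GFP and of GC content were chosen after the data were seen, and those of matched genes, of exchanged labels over the whole class, of Shox2 loss, and of the GC content of genes low in every class were chosen only after the result was seen.

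GFP was not among the planned measurements and gave a signal of its own. It stood at 1812 CPM (1787 to 1837) in cardiomyocyte-like cells of the library labelled Shox2-KO, against 1628 in the control and 1587 in the library labelled Double-KO. At 3000 UMIs per cell, 60.4% of cardiomyocyte-like cells of the library labelled Shox2-KO held a GFP UMI, against 55.1% in the control and 36.1% in the library labelled Double-KO, with 5.78%, 10.1% and 11.7% in endothelial cells. GFP-high cells made up 56.3%, 43.5% and 27.0% of cardiomyocyte-like cells with at least 3000 UMIs in these libraries.

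Nkx2-5 was 5.46-fold lower than in the control in the library labelled Shox2-KO, whose labels leave the gene intact. The tables argue against an exchange of the mutant labels, because Nkx2-5 in GFP-high cells was 0.0493 (0.0329 to 0.0711) of that in GFP-low cells of the library labelled Double-KO, and 0.0543 (0.0326 to 0.0852) outside pacemaker-like subclusters. In GFP-low cells loss of Shox2 is argued against too, because the library labelled Double-KO has the same Shox2 genotype and held Nkx2-5 at 1.615 (1.479 to 1.765) times the control there. Make-up enters this ratio, since 12 of its 469 GFP-low cells lay in pacemaker-like subclusters, against 163 of 456 in the control. Outside those subclusters Nkx2-5 stood at 234 CPM (222 to 247) against 218 (202 to 235), still not lower. The control is an unlike comparator there, since its GFP-low cells held Shox2 at 286 CPM, and at 235 outside those subclusters. GFP-low cells of the libraries labelled Shox2-KO and Double-KO held Shox2 at 6.33 and 2.98, and Nkx2-5 was 7.37-fold higher (6.24 to 8.76) in the latter. These values speak only to GFP-low cells, and not to cells in which Shox2-Cre had acted. A candidate explanation is a loss of GC-rich transcripts in the library labelled Shox2-KO, since 20% of 100 genes matched to Nkx2-5 in transcript GC content and length were at or below its log2 ratio of -2.45, against 0% for Shox2. With the GC content trend subtracted Nkx2-5 still stood at -1.53 over the class and -1.95 in GFP-high cells. At its GC content of 67.1% the genes that set the trend lie mostly below it, and the matched genes had a median of -1.50. How much of the difference remains is therefore not settled. An effect of the genotype on Nkx2-5 in GFP-high cells, and other differences of that library, stay open.

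In each of 5 classes, 185 of 3064 genes were at least 2-fold lower in the library labelled Shox2-KO than in the control, Scand1 and Pcbd2 among them. Fewer UMIs per cell are argued against, since within the control the cells at or below the median depth of the library labelled Shox2-KO had these genes at a median log2 ratio of -0.098 or more to deeper cells in each class. Loss of Shox2 is argued against as well, since the library labelled Double-KO, with the same Shox2 genotype, had them at a median of -0.146 or more to the control in each class, with lower quartiles from -0.372 to -0.275. These genes had a median of 82.0% GC in their richest 100 nt, against 73.0% over all genes (75th percentile 79.0%), which is consistent with a loss of GC-rich transcripts in that library. Its preparation and any other difference of that library or its embryos stay open, as there was 1 library per genotype.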

How the results depend on the processing

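Of the results that answer a comparison, 232 values under an alternative stayed within their counting interval (counts of lists within 1.5 times), 108 moved and 5 turned direction. Of the single genes, lists and shares, 1243 stayed, 593 moved and 10 turned. A value under 1.5-fold that changed sign, such as Nkx2-5 in the library labelled Double-KO over the control, counts as moved. Of 58 ratios of named genes, counted in each pair of libraries without the 2 of Shox2 against the control, which are counted with the results that answer a comparison, all 58 kept their direction under each setting that gave a value for them except GFP-high cells, where 56 did. The other resolutions and the other minimum UMIs gave none. The settings with GFP, with the GC trends and without low-depth and doublet-like subclusters were chosen after seeing the data. Log2 ratios below are given for the libraries labelled Shox2-KO over control (A), Double-KO over control (B) and Double-KO over Shox2-KO (C). The reported values were -0.87, -0.63 and 0.35 for the channel median, 0.29, 0.64 and 0.74 for the working atrial median, -2.45, 0.30 and 2.75 for Nkx2-5, and -4.03 and -4.42 for Shox2 in A and B, with 7, 4 and 0 list medians at least 1.5-fold lower and 1, 4 and 4 higher. The cause of each difference was not tested unless stated. No paired analysis was possible because the titles WT, Shox2-KO and Double-KO share no replicate numbers. Depth limits lists to members with at least 50 UMIs, and with 1 library per genotype no value here has an error between libraries.

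TMM factors moved the median of all genes from -0.265 to 0.018 in A, from -0.019 to -0.009 in B and from 0.254 to -0.019 in C. With them the channel median was -0.59 in A and 0.08 in C, the working atrial median 0.58 in A and 0.47 in C, Nkx2-5 -2.17 in A and 2.47 in C, Shox2 -3.745 in A, and 2 list medians were higher in A and in C. Without mitochondrial, ribosomal protein and haemoglobin genes the working atrial median was 0.34 in A. With means over cells it was 0.22 in A, and Nkx2-5 was -2.88 in A and -0.057 in B. Without a cell filter Nkx2-5 was 2.56 in C.

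The stricter cell filter gave a channel median of -1.25 in A and 0.72 in C, a working atrial median of -0.001 in A and 1.20 in C, Nkx2-5 of -3.10 in A and 3.47 in C, and Shox2 of -3.84 in A and -3.705 in B. It gave 2 list medians higher in A, 2 lower in B and 7 higher in C. The median of all genes was -0.508 in A, 0.037 in B and 0.572 in C under this filter, so all genes together shifted in A and C. Cardiomyocyte-like shares were 17.0% in the control, 7.365% in the library labelled Shox2-KO and 6.35% in that labelled Double-KO. The 5% mitochondrial limit was exceeded in 548, 765 and 417 such cells, and 182, 328 and 57 were under the stricter UMI or gene limits. Before this filter the median mitochondrial share of the class was 4.95%, 5.72% and 5.39%, against 2.45%, 3.33% and 2.74% in other cells.

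Over all kept cells, which include the other classes, the channel median was -1.14 in A, -1.15 in B and 0.063 in C, and the working atrial median -0.13 in A, -0.28 in B, against the reported direction, and 0.13 in C. Left-right genes at -0.011 in A, stress genes at 0.068 in B and ventricular genes at -0.035 in C also turned. List medians were higher in 0 in A and 1 in B, and lower in 1 in C. Nkx2-5 was -2.86 in A, -0.80 in B and 2.065 in C, and Shox2 -4.385 in A and -5.16 in B. With each cell thinned to 3000 UMIs the working atrial median was 0.13 in A and 0.875 in C, the channel median -0.825 in B, Nkx2-5 -2.88 in A, 0.10 in B and 2.98 in C, Shox2 -3.85 in A and -4.74 in B, 1 list median was lower in C, and ventricular genes turned to -1.225 in B. Without low-depth and doublet-like subclusters the channel median was -0.68 in A, the working atrial median 0.20 in A, Shox2 -3.86 in A and ventricular genes turned to -0.02 in B. With at least 200 UMIs per member, ventricular genes turned to -0.895 in B.

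In GFP-high cells the channel median was 0.046 in B, turned, and 0.73 in C, and the working atrial median 0.135 in A, and -0.10 in B and -0.09 in C, both turned. Nkx2-5 was -2.73 in A, -3.41 in B and, turned, -0.67 in C, and Shox2 -3.67 in A and -3.22 in B. Ventricular genes at -1.99 and Nppb at -0.11 in B, and Myl2 at -2.11 in C, turned, and 2 list medians were lower in B. In GFP-low cells the channel median was -1.32 in A and -1.34 in B, the working atrial median 0.11 in A and 0.455 in C, Nkx2-5 -2.19 in A and 0.69 in B, and Shox2 -5.50 in A and -6.59 in B. List medians were higher in 1 in B and 2 in C, and ventricular genes turned to -0.076 in C. These settings differ from the reported class by the division by GFP, by the minimum of 3000 UMIs per cell and by leaving out cells between the limits.

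With the transcript GC content trend subtracted the channel median was -0.57 in A and 0.079 in C, the working atrial median 0.53 in A and 0.38 in C, Nkx2-5 -1.53 in A and 1.88 in C, and Shox2 -3.80 in A, with 3 list medians lower and 2 higher in A and 2 higher in C. With the trend in the richest 100 nt subtracted these were -0.53 and 0.027, 0.41 and 0.42, -1.90 and 2.195, and -3.54, with 3 lower and 2 higher in A and 1 lower and 2 higher in C.

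The share of cardiomyocyte-like cells in subclusters dominated by 1 library was 57.2% at resolution 0.4, 63.5% at 1.5, 56.2% without list genes and 12.9% after centring each library, which removes differences between libraries by construction. Shares of cardiomyocyte-like cells in subclusters that met the pacemaker-like naming rule are given here per library. They are not compared between libraries, because subcluster 8 had no node marker among its leading genes. They were 39.8%, 13.0% and 12.6% in the control and the libraries labelled Shox2-KO and Double-KO in the reported clustering, and 68.0% in the control and 0.078% in the library labelled Shox2-KO at resolution 0.4, where a subcluster of 474 cells held as many atrial as pacemaker markers. Without list genes they were 77.2%, 0.392% and 16.6% in the same order, and after centring 33.1%, 23.8% and 16.8%. Cells with Shox2 and Nkx2-5 together were 13.3% in the control, 0.0% in the library labelled Shox2-KO (0 of 1152, which allows up to 0.26%) and 0.145% in that labelled Double-KO when thinned to 2000 UMIs, and 47.3%, 3.61% and 1.66% without thinning.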

Other observations

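Tests of the GC content trend and of cell make-up below were chosen before their values were seen, but after the difference in GFP-high cells itself and a first GC adjustment had been seen.

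GFP-high cardiomyocyte-like cells of the library labelled Shox2-KO differed from those of the control in working atrial as well as node genes. Nppa stood at 3988 against 457 CPM, Gja1 at 75.6 against 11.3 and Bmp10 at 29.5 against 0.706, while Gja5 stood at 37.3 against 33.2 and Nppb at 26.1 against 40.8. Isl1 stood at 49.2 against 136, Tbx3 at 14.6 against 55.0, Smoc2 at 97.9 against 440 and Vsnl1 at 389 against 587, while Tbx18 stood at 55.5 against 54.0 and Hcn4 at 131 against 193 (1.47-fold lower, 1.34 to 1.61, with adjusted log2 ratios of -0.247 for GC content and -0.068 for the richest 100 nt). The medians were -1.69 for pacemaker transcription factors, 0.14 for working atrial genes and -0.73 for channels, the last inside the 1.5-fold margin after either adjustment (-0.435 and -0.497). Within the library labelled Double-KO, Nppa was 33.5-fold and Nppb 44.1-fold lower in GFP-high than in GFP-low cells, and Hcn4 was 16.4-fold and Smoc2 27.1-fold higher. The directions were the same in the other libraries. In the same order the folds were 4.97, 2.48, 8.24 and 9.78 in the library labelled Shox2-KO, and 6.16, 2.94, 1.44 and 1.18 in the control. Control GFP-low cells still held Hcn4 at 134 CPM, against 15.9 in the library labelled Shox2-KO and 13.6 in that labelled Double-KO. Since the control was heterozygous for Shox2-Cre and the mutant libraries homozygous, the size of these folds may compare unlike sets of cells.

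Some clusters held cells of 2 of the 3 libraries, which does not show that their cell types were absent from the other, since many clusters separated by library. The library labelled Shox2-KO held 0 cells of 5656 (up to 0.053%) in the lung or foregut epithelial cluster, in a smooth muscle cluster led by Mylk, Actg2 and Myh11, and in unnamed clusters led by Cxcl14, Osr2 and Foxf1 or by the cartilage genes Col2a1, Col9a1 and Matn4. Unnamed clusters held 13.4% of the library labelled Double-KO and 6.68% of the control.

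In GFP-high cells the median log2 ratio of pacemaker channel genes was 0.73 for the library labelled Double-KO over that labelled Shox2-KO. With the GC content trend subtracted it was 0.41 (quartiles of the members 0.233 to 0.938), and 0.354 (0.099 to 0.703) with the trend in the richest 100 nt subtracted. Each adjustment also takes out the median over all genes in these cells, which was 0.328, so the drop does not show how much comes from GC content. The rule that the members' quartiles must lie on 1 side of the bound was set after these values were seen. Hcn4 was 1.64-fold higher (1.39 to 1.95) within subclusters that met the pacemaker-like naming rule, which does not settle the make-up of GFP-high cells, because in the library labelled Shox2-KO that name rests on subcluster 8. That subcluster had no node marker among its 10 leading genes, although the cells of that library under the name held Hcn4 at 194 CPM and Isl1 at 104. Subclusters under that name held 52.7% of GFP-high cells in the control, 23.5% in the library labelled Shox2-KO and 41.5% in that labelled Double-KO. The same limit of the name applies to these shares. The GC trend, the make-up of GFP-high cells by dissection and a genotype effect of Nkx2-5 cannot be told apart, because the members spread widely and there was 1 library per genotype.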
